A study of Mus musculus with 8 samples.

How the data were processed

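Primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, were sorted from mouse embryos at embryonic day 10.5, 11.5 and 12.5 (E10.5, E11.5 and E12.5). The measurement was AbaSeq, in which the enzyme AbaSI cuts DNA near 5-hydroxymethylcytosine (5hmC, an oxidised form of 5-methylcytosine made by TET enzymes) that carries a glucose, and the cut ends are sequenced. Each of the 8 libraries was made from 10000 sorted cells with 16 cycles of PCR. They form 4 groups of 2 libraries each: E10.5, E11.5, E12.5 female and E12.5 male.

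Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with Bowtie 0.12.8 to the mouse genome build mm9. The deposited values are signal per CpG, and there are 4 tables, with both libraries of a group in a single column. Each table lists the same 21222488 CpGs, strands combined, with 0 where no read was assigned. Within a tolerance of 1e-06, 100% of the values in each deposited table are a whole number multiplied by 1 factor per group, and the whole numbers were taken as reads. The factor was 0.276 at E10.5, 0.424 at E11.5, 0.262 in E12.5 female and 0.480 in E12.5 male cells. The signal is not scaled to a common total, and how the authors chose the factor is not stated in the labels or notes. Ratios of signal between groups depend on that factor, while values relative to a group's own autosomal mean do not.

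Reads per CpG were used for depth and for intervals. Levels are mean signal over CpGs, with CpGs of 0 included. A chromosome level relative to autosomes is its mean signal divided by the mean over the 19 autosomes of the same group. For CpG density, each CpG was placed in a class by the number of other CpGs within 250 bp on each side, and the level of a class over all chromosomes was divided by the autosomal mean. For regions, the genome was divided into 10 kb windows and those with at least 20 CpGs were kept. The log2 change of a window was taken after adding a pseudocount of 10% of the median window level. The windows named in each comparison follow a rule set before the data were examined: the 5 largest and the 5 lowest log2 changes among windows on any chromosome with at least 50 CpGs and a mean level over both groups at or above the median window.

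Each group has 1 pooled column, so no replicate error and no test between groups could be computed. Confidence intervals at 95% treat reads as independent counts and cover counting error only, since PCR copies are not separate molecules. Intervals of a ratio of reads are exact binomial (Clopper-Pearson). Where a group had 0 reads, the limit is 3 counts over the region. As a further view of precision, the odd-numbered and even-numbered CpGs of each window were compared within each group. These are different sites, so the comparison also holds lasting differences between CpGs, and it holds no variation between libraries. The spread over autosomes is given as a range.

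Alternatives covered the normalisation of each group, the pseudocount, window sizes of 2 kb and 100 kb, the minimum number of CpGs, capping values at the 99.9th percentile, neighbour distances of 100 bp and 500 bp, and the share of CpGs with reads in place of mean signal. The cap was set by each group's own values above 0. It stood at a signal of 24.6 at E10.5, 30.9 at E11.5, 28.6 in E12.5 female and 87.9 in E12.5 male cells. Capped comparisons with male cells therefore trim the groups at unlike levels. After the data had been seen, CpGs in recurring spacing patterns were also marked: a run of 5 consecutive spacings between 6 neighbouring CpGs that occurs at least 20 times in the genome, a proxy for repeated sequence that needs no annotation. CpGs outside recurring patterns are those for which every such run occurs once in the genome, and their levels are relative to autosomal CpGs of the same kind. The windows were tested on simulated data drawn from the E11.5 group: 100 of 100 windows raised 4-fold and 100 of 100 lowered 4-fold were recovered, and 190 of 200 ratio intervals held the true ratio. The simulated reads were independent and spread evenly over the CpGs of a window. Changed windows had at least 50 CpGs and a level at or above the median. The simulation therefore checks the computation only. It does not give the precision of the real reads, which were clumped on single CpGs. In the same simulation the pseudocount shrank a true median log2 change of -1 to -0.89.

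Promoter, gene-body, gene-list and named-gene results were planned and are not analysed here, because the gene annotation at hand is on another build than mm9. Windows are therefore given by mm9 position alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.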

Results

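5hmC was profiled at 21222488 CpGs in PGCs at E10.5, E11.5 and E12.5, with female and male cells separate at E12.5, and each group was the pool of 2 libraries. The pools held 229645031 reads at E10.5, 115093652 at E11.5, 63005321 in E12.5 female and 39715924 in E12.5 male cells. Reads were present at 76.4% of CpGs at E10.5, 60.1% at E11.5, 28.7% in E12.5 female and 13.8% in E12.5 male cells. Among CpGs with reads, the median was 11 reads at E10.5, 6 at E11.5, 6 in E12.5 female and 2 in E12.5 male cells. No group had replicate columns, so differences are given as sizes with their spread over autosomes or their counting intervals, and none was tested.

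The first comparison asks how the genome-wide 5hmC level changed over these days. The autosomal mean signal was 3.09 at E10.5, with single autosomes between 2.76 (chromosome 7) and 3.28 (chromosome 11). It was 2.36 at E11.5, with autosomes between 2.10 (chromosome 7) and 2.53 (chromosome 18). At E12.5 it was 0.785 in female cells, between 0.697 (chromosome 7) and 0.848 (chromosome 10), and 0.920 in male cells, between 0.828 (chromosome 7) and 0.983 (chromosome 10). E11.5 signal was thus 0.765 of E10.5 signal, and the ratio lay between 0.704 and 0.794 on each of the 19 autosomes. Relative to E11.5, female signal was 0.333 (autosomes 0.322 to 0.353) and male signal 0.390 (0.369 to 0.414).

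Female autosomal signal was 0.854 of male signal at E12.5, between 0.780 and 0.904 on single autosomes. Counted as the share of CpGs with reads, the order was the other way, with 29% of autosomal CpGs in female and 14.1% in male cells. Reads themselves numbered 0.499 of E10.5 at E11.5, 0.537 of E11.5 in female cells and 0.344 of E11.5 in male cells. These ratios of signal rest on the deposited factors.

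The X chromosome was compared with the autosomes to follow its 5hmC in each sex and stage. Its level was 0.337 of the autosomal mean at E10.5, 0.422 at E11.5, 0.842 in E12.5 female and 0.478 in E12.5 male cells. Single autosomes lay between 0.888 and 1.08 in these groups, so the mean over X was below them in each group. Counted as the share of CpGs with reads over that of autosomes, X was at 0.714, 0.588, 0.851 and 0.581 in the same order, so E10.5 was then above E11.5 and male cells, and male cells just below E11.5. On the deposited scale, X signal was 1.04 at E10.5, 0.995 at E11.5, 0.661 in female and 0.440 in male cells. The female to male ratio was thus 1.5 on X, against 0.854 on autosomes. The number of X chromosomes differs between the sexes, so this ratio does not measure 5hmC per copy.

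The position of X depended on CpG density. Over CpGs outside recurring spacing patterns and against autosomal CpGs of the same density class, X in female cells was at 0.819 for 0 to 2 neighbours and 0.843 for 3 to 5, but at 1.19 for 6 to 10, 1.63 for 11 to 20 and 2.28 for 21 or more. In the densest class X was at 0.771 at E10.5, 1.14 at E11.5 and 1.31 in male cells, and below 1 in each other class of these groups.

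**Figure D1:**
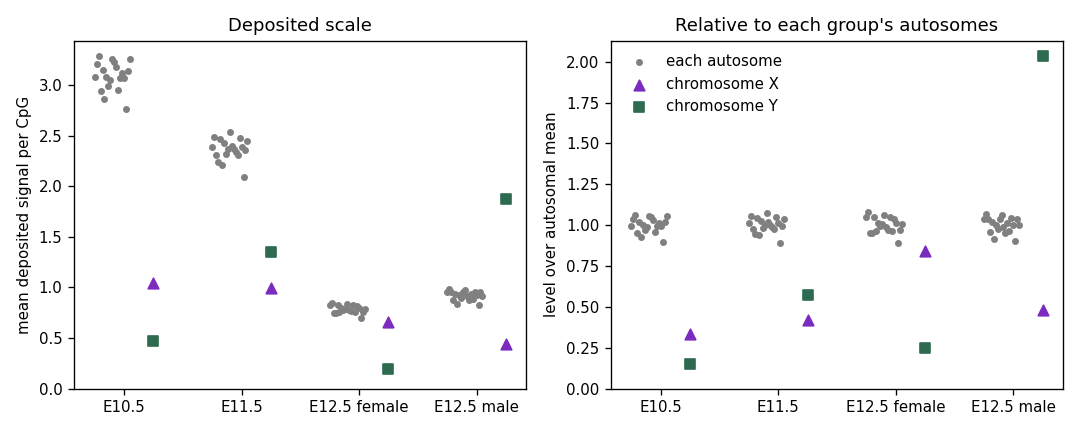
Mean 5hmC signal per CpG of each autosome (grey points), X and Y in the 4 groups, on the deposited scale (left) and divided by the autosomal mean of the group (right). On the right, X lies at 0.337, 0.422, 0.842 and 0.478 and Y at 0.152, 0.571, 0.25 and 2.03 in E10.5, E11.5, E12.5 female and E12.5 male cells, while autosomes lie between 0.888 and 1.08.

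The difference between groups was spread along X. Over CpGs outside recurring spacing patterns, in 34 bins of 5 Mb, the level was below 0.5 of the autosomal mean in 28 bins at E10.5, 25 at E11.5, 1 in E12.5 female and 18 in E12.5 male cells. Median bin levels were 0.351, 0.437, 0.853 and 0.486 in the same order. The bin between 25 and 30 Mb was the lowest in each group, at 0.0314, 0.0961, 0.362 and 0.212. The last bin, from 165 Mb, had the highest level in female cells, 1.84, and in male cells, 1.94, and was at 1.03 at E11.5. It holds 8696 CpGs, the fewest of the bins.

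**Figure D2:**
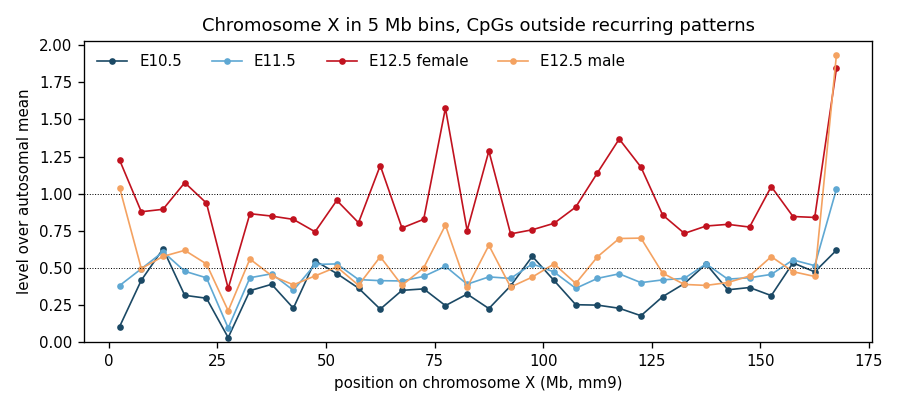
5hmC signal along the X chromosome in bins of 5 Mb (mm9), over CpGs outside recurring spacing patterns and divided by the autosomal mean of such CpGs, with a line per group. The E12.5 female line has a median of 0.853 and the E10.5 line of 0.351.

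Y chromosome signal separated the sexes at E12.5. Over its 17626 CpGs the level relative to autosomes was 0.152 at E10.5 (30000 reads), 0.571 at E11.5 (56092 reads), 0.25 in E12.5 female (13189 reads) and 2.03 in E12.5 male cells (68674 reads). The female to male ratio of Y signal was 0.105. Female cells carry no Y, and where their Y reads came from was not tested. Nor was it tested why the male level was above the autosomal mean. Adjacent windows at 2870001 to 2890000, singled out after their values were seen, held 31.9% of the male Y reads and 20.2% of the female Y reads on 128 CpGs. Without them the Y levels were 0.119, 0.428, 0.201 and 1.40 in the order of the groups above. As a share of CpGs with reads over that of autosomes, Y was at 0.358, 0.428, 0.202 and 1.14, so female cells were then below E10.5.

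5hmC was unevenly spread over CpG density at each stage. CpGs with 21 or more neighbours had 0.0807 of the autosomal mean at E10.5, 0.0987 at E11.5, 0.169 in E12.5 female and 0.183 in E12.5 male cells. Across single autosomes the level of this class ran from 0.0571 to 0.111, 0.0741 to 0.127, 0.110 to 0.217 and 0.140 to 0.224 in the same order. The highest class was 6 to 10 neighbours in each group, at 1.28, 1.21, 1.16 and 1.2. On X alone, and among CpGs with no other CpG 20 to 23 bp away in male cells, it was the class of 11 to 20 neighbours at E12.5. CpGs with 0 to 2 neighbours were at 0.810 at E10.5, 0.896 at E11.5, 0.974 in female and 0.863 in male cells.

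The densest class was higher at E12.5 than at E10.5 relative to the autosomal mean and lower on the deposited scale, where its signal was 0.249 at E10.5, 0.233 at E11.5, 0.133 in female and 0.168 in male cells. Reads were present at 14.9% of CpGs of this class at E10.5, 7.40% at E11.5, 4.73% in female and 2.66% in male cells. It makes up 7.96% of all CpGs, and 81.6% of its CpGs had no read in any group. Within it, 23.9% of CpGs belonged to recurring spacing patterns. CpGs with no repeated run of spacings were only 480235 of the 1690063 in this class, since runs that occur 2 to 19 times are left out too. For them, and relative to autosomal CpGs of that kind, the levels were closer together, at 0.163, 0.162, 0.201 and 0.239. Another CpG lay 20 to 23 bp away for 52.1% of CpGs in the densest class, against 2.19% in that of 0 to 2 neighbours. Signal at such spacing was below that of isolated CpGs, and without these CpGs the densest class was higher in each group.

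**Figure D3:**
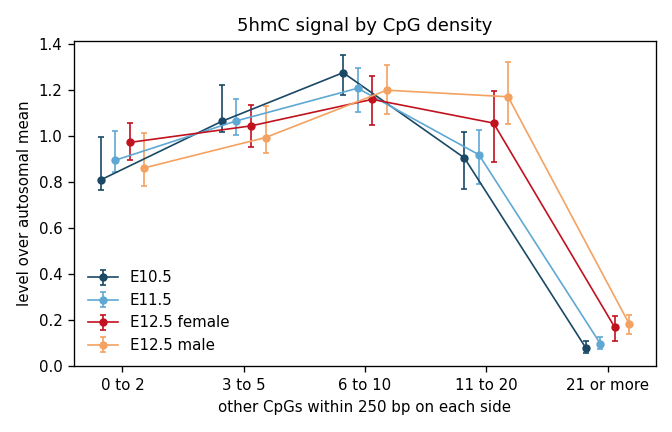
5hmC signal by the number of CpGs within 250 bp, divided by the autosomal mean, for the 4 groups, with points for all chromosomes and bars for the range over 19 autosomes. The class of 21 or more neighbours lies at 0.0807 at E10.5 and 0.183 in E12.5 male cells.

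Changes between stages were next compared in 239017 autosomal and 16114 X windows of 10 kb. The median autosomal window held 735 reads at E10.5, 392 at E11.5, 204 in E12.5 female and 112 in E12.5 male cells, on 59, 47, 22 and 10 CpGs. Across windows, which are not independent replicates, odd and even CpGs of a window had a Spearman correlation of 0.944 at E10.5, 0.814 at E11.5, 0.545 in female and 0.320 in male cells.

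From E10.5 to E11.5 the median autosomal window changed by a log2 of -0.30 (middle 50% of windows -0.56 to 0.04), with median levels of 2.77 at E10.5 and 2.26 at E11.5. Signal was lower in 72.0% of windows and higher in 27.3%. After each group was divided by its autosomal mean, 44.4% were lower and 54.9% higher, with a median of 0.049. The levels at both stages had a Spearman correlation of 0.839 across windows. The spread of changes between windows (SD 0.50) exceeded that derived from odd and even CpGs (0.29). X windows had a median of 0, with 48.5% lower and 47.6% higher.

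The windows with the highest change at E11.5 held a large share of their reads at single CpGs. They lay on chromosome 6 at 89640001, 14 at 90700001, 17 at 38820001, 2 at 46150001 and 17 at 77150001, with log2 changes of 2.34 to 2.96. In the first, of 98 CpGs, signal was 0.477 at E10.5 and 4.87 at E11.5, a ratio of 10.2 (interval 8.68 to 12.1). A single CpG held 78.3% of its E11.5 reads, and between 44.8% and 80.4% in the 5 windows. Recurring patterns made up 85.7% of its CpGs and at least 13.6% in each. With the highest values capped, the log2 change of the first was 1.21 and those of the 5 windows lay between 0.74 and 1.21.

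The windows with the lowest change at E11.5 held reads at most of their CpGs at E10.5. They lay on chromosome 6 at 36880001, 7 at 119830001, 8 at 90210001, 3 at 30040001 and 1 at 160630001, with log2 changes of -1.81 to -1.63. In the first, of 62 CpGs, signal was 4.32 at E10.5 and 1.11 at E11.5, a ratio of 0.258 (interval 0.217 to 0.305). The largest CpG held between 2.89% and 11.2% of reads in either group.

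From E11.5 to E12.5 in female cells the median autosomal window changed by -1.44 (middle 50% -1.74 to -1.03), with median levels of 2.26 and 0.705. Signal was lower in 97.2% of windows and higher in 2.01%. Relative to the autosomal means, 55.3% were lower and 44.0% higher, with a median of -0.067. The levels had a Spearman correlation of 0.680 across windows, and the SD of changes was 0.57 against 0.42 from odd and even CpGs. X windows had a median of -0.46 and were lower in 72.4%.

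The windows with higher signal in E12.5 female cells were again dominated by single CpGs. They lay on chromosome 15 at 46700001 and 5320001, X at 74310001, 3 at 6290001 and X at 81630001, with log2 changes of 1.12 to 2.20. In the first, of 117 CpGs, signal was 0.866 at E11.5 and 4.59 in female cells, a ratio of 5.30 (interval 4.63 to 6.08), and 95.6% of the female reads were on a single CpG. This share was at least 78.0% in each of the 5, and recurring patterns made up 52.4% to 88.9% of their CpGs. With the highest values capped, the changes of both windows on chromosome 15 and of 74310001 on X were 0.014, 0.27 and 0.21, and the other windows changed direction, to -0.040 and -0.053.

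The lowest female windows lay on chromosome 6 at 61010001, Y at 2880001 and 610001, 3 at 143070001 and 2 at 71550001, with log2 changes of -3.41 to -3.22. On chromosome 6, over 61 CpGs, signal was 2.86 at E11.5 and 0.116 in female cells (27 reads), a ratio of 0.0406 (interval 0.0264 to 0.0599). The Y window at 2880001, of 73 CpGs, had 62.3 at E11.5 and 6.14 in female cells, against 103 in male cells, and its change with the highest values capped was -1.78.

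From E11.5 to E12.5 in male cells the median autosomal window changed by -1.39 (middle 50% -2.11 to -0.74), with median levels of 2.26 and 0.711. Signal was lower in 91.9% of windows and higher in 7.37%. Relative to the autosomal means, 58.7% were lower and 40.6% higher, with a median of -0.23. The levels had a Spearman correlation of 0.479 across windows. The SD of changes was 1.01 against 0.81 from odd and even CpGs. X windows had a median of -1.26 and were lower in 82.7%.

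Male windows with higher signal lay on chromosome 7 at 12640001, Y at 280001, 19 at 9450001, 2 at 36910001 and 14 at 112740001, with log2 changes of 1.92 to 2.49. In the first, of 72 CpGs, signal was 0.412 at E11.5 and 3.09 in male cells, a ratio of 7.50 (interval 5.82 to 9.78). The largest CpG held 17.4% to 33.9% of the male reads in these windows. Male windows with lower signal lay on chromosome 1 at 81540001, 4 at 81920001, 14 at 8690001, 10 at 13020001 and 6 at 88240001, with log2 changes of -4.41 to -4.37. In the first, of 53 CpGs, signal was 3.80 at E11.5 and 0.0181 in male cells, from 2 reads, a ratio of 0.00477 (interval 0.000576 to 0.0173). Male reads numbered 2 to 9 in the 5 windows, where female signal was 0.790 to 1.14.

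Between female and male cells at E12.5 the median autosomal window differed by -0.0017 (middle 50% -0.57 to 0.69), with median levels of 0.705 and 0.711. Female signal was lower in 50.1% of windows and higher in 49.1%. Relative to the autosomal means it was lower in 41.9% and higher in 57.2%, with a median of 0.18. The levels had a Spearman correlation of 0.512 across windows of 10 kb and 0.788 across windows of 100 kb. The SD of differences, 0.93, was close to the 0.85 derived from odd and even CpGs. By that yardstick, which also holds differences between CpGs of a window, differences of single windows were mostly not resolved. On X, whose number of copies differs between the sexes, the median was 0.79, and female signal was higher in 74.1% of windows.

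The windows with the highest female to male difference lay on X at 118470001, 94130001 and 112930001, chromosome 9 at 30630001 and 5 at 86040001, with log2 differences of 3.18 to 3.45. At 118470001 on X, over 68 CpGs, signal was 2.05 in female and 0.0353 in male cells (5 reads), a ratio of 58.0 (interval 24.7 to 179). On chromosome 5 the ratio of 158 rested on 1 male read (interval 28.2 to 6278). The lowest windows were all on Y, which female cells lack, at 2880001, 280001, 610001, 2870001 and 1020001, with log2 differences of -4.03 to -3.50. At 2880001 female signal was 6.14 and male signal 103, a ratio of 0.0598 (interval 0.0569 to 0.0629). The female signal there came from 1707 reads on 47 CpGs, and their origin was not tested. With the highest values capped, the differences at 2880001 and 2870001 were -2.89 and -2.49. At 1020001, over 52 CpGs, female cells had 0 reads and male cells 188, so female signal was at least 114.7-fold lower, taking 3 counts over the window as the limit of a count of 0.

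**Figure D4:**
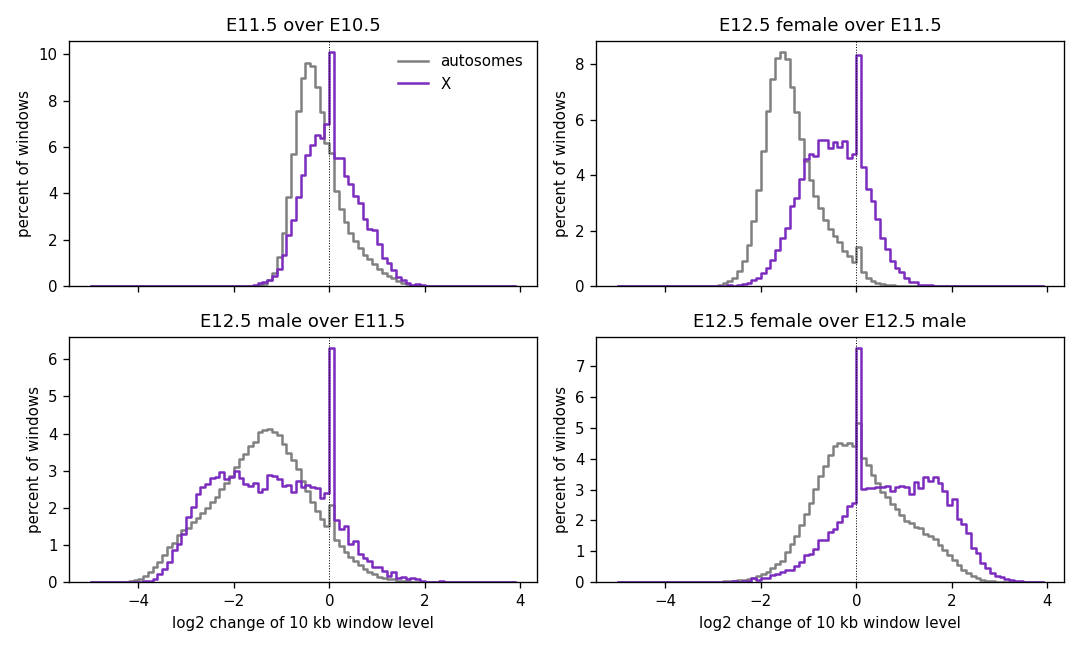
Distribution of log2 changes of 10 kb windows in the 4 comparisons, for autosomes and X, as the percent of windows per bin. Autosomal medians are -0.30, -1.44, -1.39 and -0.0017 and X medians 0, -0.46, -1.26 and 0.79.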

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

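The tests of the X chromosome, and the check of each listed direction relative to autosomal means, were chosen after the values had been seen. Each sex was set against E11.5, and results where female and male cells moved in opposite directions on the deposited scale are listed with the female minus male difference in log2 change, computed without a pseudocount. Relative to the autosomal means, the directions were still opposite in 8 of these 13 results, which are those on the Y chromosome as a whole, in Y windows and in X windows. Only the windows named above were examined. Those on X and Y were named for their large difference between the sexes, so their opposite directions follow in part from that choice. The share of such directions over all windows was not computed. With 1 pooled column per group, these differences between the sexes were not tested.

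Y chromosome signal was lower in female and higher in male cells than at E11.5. Female cells carry no Y, so these directions follow its presence and do not measure 5hmC per copy. It was 1.35 at E11.5, 0.196 in E12.5 female and 1.87 in E12.5 male cells, a difference of -3.25. The Y windows at 2880001, 2870001, 610001 and 280001 differed by -4.06, -3.60, -5.12 and -5.51, and with the pseudocount used in the report by -4.03, -3.56, -3.99 and -4.02. In the first, signal was 62.3 at E11.5, 6.14 in female and 103 in male cells.

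On X, windows at 118470001, 94130001 and 112930001 differed by 5.86, 4.48 and 4.42, and with the pseudocount by 3.45, 3.22 and 3.22, with female signal of 2.05, 2.39 and 2.47 against 5, 17 and 13 reads in male cells. X CpGs with 21 or more neighbours had 0.242 at E11.5, 0.247 in female and 0.194 in male cells, a difference of 0.35, but relative to autosomes they were at 0.102, 0.315 and 0.211, higher in both sexes than at E11.5. On autosomes, the window on chromosome 14 at 112740001 differed by -2.19, with signal of 1.37 at E11.5, 1.24 in female and 5.64 in male cells. Smaller differences were 0.75 on chromosome 14 at 90700001, -0.41 on 17 at 38820001 and -0.45 on 17 at 77150001, in windows where single CpGs held much of the E11.5 signal. Relative to the autosomal means, these 4 autosomal windows were higher in both sexes than at E11.5, at 0.581, 1.57 and 6.13 in the window at 112740001, so their opposite directions rest on the deposited factors.

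The X level over autosomes outside recurring patterns was 0.386 at E10.5 and 0.470 at E11.5, against 0.911 in E12.5 female and 0.505 in E12.5 male cells, and the value at E10.5 is below 0.467, 50% of the lowest autosome, which argues against pooling embryos of both sexes as the whole cause. As a share of CpGs with reads X was at 0.714 at E10.5, but that measure counts a CpG with 1 read like one with many and 77.5% of autosomal CpGs had reads, so it does not give a level per copy. At E11.5 the level of 0.470 lies between 50% of the lowest autosome, 0.463, and of the highest, 0.526. It was below the levels of both sexes at E12.5, 0.505 in male and 0.911 in female cells. A pool of cells at those levels would lie between them, so no mixture would reach 0.470. Over CpGs with 0 to 2 neighbours, however, the male level was below that of E11.5, at 0.452 against 0.472. If X per copy were at 50% of an autosome, a level of 0.470 would need mostly male cells. The Y level at E11.5, 0.571, was nearer that of E12.5 female cells, 0.25, than that of male cells, 2.03. This argues against a mostly male pool if the Y level per copy was alike at both days. Y at E10.5 was at 0.152, below E12.5 female cells, so that level may not be steady. Female cells carry no Y and still had 0.25, so Y levels may also hold reads of other origin. Whether X had a lower level per copy at E11.5 was therefore not settled. The density and repeats of X do not account for the change, since on CpGs matched for density outside recurring patterns the level was still 2.23 times higher in female cells than at E10.5. Female and male cells differ in their number of X chromosomes. The higher level in female than in male cells therefore does not by itself show a difference in 5hmC per copy. A change in 5hmC on X with stage may explain part of the pattern. This stays an untested hypothesis because each stage and sex has a single pooled column.

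Signal was also present in the mitochondrial genome, which has no comparison of its own in the report and whose 287 CpGs are included in values over all chromosomes. Its level was 3.15 at E10.5 (3271 reads), 6.30 at E11.5 (4265 reads), 7.03 in E12.5 female (7684 reads) and 8.34 in E12.5 male cells (4984 reads). Relative to the autosomal mean, which does not depend on the deposited factors, it was 1.02, 2.67, 8.95 and 9.07. The limits of a count of 0 over these CpGs were 0.00289, 0.00443, 0.00274 and 0.00502.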

How the results depend on the processing

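Results were recomputed under the alternatives fixed before the data were examined, and under some chosen after seeing the data: CpGs outside recurring spacing patterns, CpGs with no other CpG 20 to 23 bp away, the Y chromosome without its 2 highest windows, and reads thinned to equal totals. Because the counting intervals of whole-genome values are very narrow, 101 of 124 recomputed group levels and medians left them, 18 stayed inside and 5 changed sign. No paired analysis was possible because each group has a single pooled column, so replicate numbers mark no column. For the same reason a replicate block, leaving out a replicate and a count test across libraries were not run, and the promoter and gene-list alternatives were not run because those results are not analysed here.

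Ratios of genome-wide signal are listed as E11.5 over E10.5, E12.5 female over E11.5, E12.5 male over E11.5 and E12.5 female over E12.5 male, and were 0.765, 0.333, 0.390 and 0.854 as reported. Capping the highest values gave 0.765, 0.332, 0.389 and 0.852. All chromosomes together gave 0.769, 0.339, 0.391 and 0.867. CpGs outside recurring patterns gave 0.755, 0.323, 0.377 and 0.857. The share of CpGs with a value above 0 gave 0.791, 0.472, 0.230 and 2.05, so the female to male ratio changed sides of 1. After thinning to equal reads these share ratios were 0.851, 0.540, 0.280 and 1.93. The restriction to CpGs with a value in at least 1 group leaves each ratio as it is by construction.

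Group values from here on are listed as E10.5, E11.5, E12.5 female and E12.5 male. The X level over autosomes, 0.337, 0.422, 0.842 and 0.478 as reported, was 0.337, 0.418, 0.834 and 0.473 with the cap, 0.401, 0.443, 0.769 and 0.425 over CpGs with 0 to 2 neighbours, and 0.386, 0.470, 0.911 and 0.505 outside recurring patterns. Counted as shares of CpGs with a value above 0, it was 0.714, 0.588, 0.851 and 0.581. In that measure X was higher at E10.5 than at E11.5 or in E12.5 male cells, and Y lower in E12.5 female cells than at E10.5, the other order from that reported. The male X level was also below that of E11.5 as a share and over CpGs with 0 to 2 neighbours, and the cause of these turns was not tested. The Y level, 0.152, 0.571, 0.25 and 2.03 as reported, was 0.129, 0.379, 0.241 and 1.43 with the cap, 0.358, 0.428, 0.202 and 1.14 as a share, and 0.227, 0.647, 0.227 and 2.11 over CpGs with 0 to 2 neighbours. Outside recurring patterns it was 0.204, 0.746, 0.289 and 2.76, and without its 2 highest windows 0.119, 0.428, 0.201 and 1.40. Under each of these settings the E12.5 female X level stayed the highest of the 4 X levels and the E12.5 male Y level the highest of the 4 Y levels.

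The level of CpGs with 21 or more neighbours, 0.0807, 0.0987, 0.169 and 0.183 as reported, was 0.00921, 0.00793, 0.0165 and 0.0169 when neighbours were counted within 100 bp and 0.491, 0.502, 0.619 and 0.690 within 500 bp. The cap gave 0.0807, 0.0962, 0.158 and 0.179, autosomes alone 0.0817, 0.0985, 0.163 and 0.182, and X alone over the X mean 0.169, 0.243, 0.374 and 0.441. Outside recurring patterns it was 0.163, 0.162, 0.201 and 0.239, and with no CpG 20 to 23 bp away 0.116, 0.142, 0.243 and 0.264. Within 100 bp, and outside recurring patterns, the E11.5 level was below the E10.5 level, the other order from that reported, and the cause was not tested. Relative to all autosomal CpGs, the class of 11 to 20 neighbours was above that of 6 to 10 in male cells with no CpG 20 to 23 bp away, at 1.30 against 1.27. On X alone it was so in female cells, at 1.29 against 1.19, and in male cells, at 0.824 against 0.739.

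Median log2 changes of autosomal windows, in the order used for the ratios, were -0.30, -1.44, -1.39 and -0.0017 as reported. Dividing each group by its autosomal mean gave 0.049, -0.067, -0.23 and 0.18, and dividing by the median of its upper windows gave 0.088, -0.016, -0.30 and 0.31, so both turned the sign of E11.5 over E10.5 and of female over male. These settings remove the genome-wide change by construction. Windows of 2 kb gave -0.46, -1.52, -1.53 and 0.15 and windows of 100 kb -0.30, -1.40, -1.24 and -0.15, where the female to male median also changed sign between sizes, and the cause was not tested. Pseudocounts of 1% and 50% gave -0.32, -1.64, -1.59 and -0.0020, and -0.23, -0.96, -0.92 and -0.00087. A minimum of 50 CpGs gave -0.36, -1.47, -1.36 and -0.060. The cap and no minimum left each median within its interval. Of 200 values of the 40 named windows, 2 changed sign, both with the cap and both in the E12.5 female comparison with E11.5: the windows at 6290001 on chromosome 3 and 81630001 on X were at -0.040 and -0.053, since the cap lowers the single sites that held most of their reads. The cap also brought the other female windows above E11.5 to between 0.014 and 0.27, the E11.5 windows above E10.5 to between 0.74 and 1.21, and the Y windows at 2880001 and 2870001 to changes between -2.89 and -1.78. E12.5 male windows rest on the fewest reads and CpGs, with a median of 112 reads on 10 CpGs per 10 kb window against 735 reads on 59 CpGs at E10.5.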

Other observations

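The recurring patterns, clusters and position classes, and the tests of an even background and of male read concentration, were chosen after the data had been seen. The tests on CpGs read at E10.5 and on thinned reads were set before their results were seen.

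CpGs in recurring spacing patterns had higher 5hmC at later stages relative to the rest of the genome. They are 6.63% of autosomal CpGs, and their level relative to the autosomal mean was 0.0698 at E10.5, 0.165 at E11.5, 0.388 in E12.5 female and 0.408 in E12.5 male cells. On the deposited scale their signal was 0.215, 0.390, 0.304 and 0.375, while that of CpGs in unique surroundings was 3.54, 2.67, 0.863 and 1.01. No read in any group was found at 83.3% of them. The patterns differed in level: 1 with 1571 copies had relative levels of 0.0584, 0.233, 0.75 and 0.758, and another with 2421 copies had 0.00184, 0.00581, 0.0153 and 0.010. Mitochondrial CpGs also had more signal relative to autosomes at later stages, from 1.02 at E10.5 to 9.07 in male cells. Whether this is linked, or follows the number of mitochondrial copies, was not tested.

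Repeat positions that only the later libraries could place reads at are argued against as the whole cause. Among CpGs with a read at E10.5, the level of recurring over other CpGs was still 5.36 times higher in female cells than at E10.5, and at least 4.39 times on each autosome. Reads piled on single sites are argued against too, since the detection of recurring over other CpGs was 3.57 times higher than in E10.5 reads thinned to match, and at least 3.07 times on each autosome. A larger even background would also have raised dense CpGs outside recurring patterns, but by less, since they started from a higher level than recurring CpGs. They were 1.23 times higher, and the rise that such a background would give was not computed. A background that grows with the number of copies of a sequence would not raise them, so 1.23 cannot exclude it. That value covers only 480235 of the 1690063 CpGs of the densest class. A difference with stage in the 5hmC of repeated sequence may underlie the pattern, as a hypothesis found in the same data and not tested itself, and the deposited factors leave open how its absolute level changed.

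E12.5 male reads lay on few CpGs. The 1% of CpGs with most reads held 48.2% of male reads, against 6.33% at E10.5, 8.93% at E11.5 and 18.0% in female cells. Lower depth is argued against as the whole cause, since after thinning to equal reads the lowest other group still had reads at 1.93 times as many CpGs as male cells. Few starting molecules copied many times may be a cause: male CpGs with 40 to 79 reads were 1.95 times as many as those with 10 to 19 reads, against at most 0.163 in the other groups. Less 5hmC in male than in female cells cannot be told apart from this, because the deposited autosomal ratio of 0.854 rests on a factor that is not explained.

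Some dense CpG clusters carried high 5hmC throughout. Of 10325 autosomal clusters of at least 30 CpGs with few recurring patterns, 155 at E10.5, 227 at E11.5, 191 in female and 351 in male cells were at or above the autosomal mean, and 44 were so in each group. Shared clusters numbered 122 between E10.5 and E11.5, where independent lists would share 3.41, and 119 between female and male cells, against 6.49. Traits of a cluster that all groups have in common, such as its CpG spacing, also make lists overlap, so the excess does not measure 5hmC alone. Some male clusters rest on few CpGs, such as 8 of 30 with reads on chromosome 5 at 114064202. A cluster of 32 CpGs on chromosome 8 at 108502909 to 108503390, named after its values were seen, had relative levels of 1.36, 3.15, 4.93 and 6.12 in the order of the groups. Not all of them rose at each step: a cluster on chromosome 15 at 76003400 was at 1.63, 3.19, 3.08 and 1.84.

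Levels near the start of the autosomes differed by stage. Outside recurring patterns, CpGs 2 to 5 Mb from the start were at 0.841 of the mean of such autosomal CpGs at E10.5, 0.972 at E11.5, 1.18 in female and 1.22 in male cells, and above 1 on 4, 6, 15 and 15 of 19 autosomes. CpGs 5 to 10 Mb from the last CpG were at 1.19, 1.15, 1.08 and 1.11.

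CpGs with the next CpG 21 to 22 bp away had 0.654, 0.609, 0.580 and 0.592 of the signal of isolated CpGs in the order of the groups, against 1.23, 1.19, 1.14 and 1.2 where it was 10 to 19 bp away.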
